A study of Mus musculus with 2 samples.

How the data were processed

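The files came from DNase-seq of mouse hippocampus, 2 samples in 1 group, per the labels biological replicates 1 and 2, each a pool of 2 biosamples. Both carry the same donor label, and whether the pools share animals is not given in the sources used here. Per the labels the tissue was layer of hippocampus and the assembly was mm10. The aligner, the peak and footprint callers and their versions are not given in the sources used here, and whether reads of the CAST/EiJ allele were mapped as well as those of C57BL/6J was not analysed here.

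For each sample the authors deposited 2 peak lists, a file of false discovery rates and a list of footprints, all called per sample. In the peak lists the deposited value per peak is a height (unit: signal). It is the authors' own value, and its scale is not stated. All values under 200 steps were whole multiples of 1 step within 0.1 step (step 0.00656 in replicate 1 and 0.00646 in replicate 2), which fits scaled cut counts. The last column holds the constant 75 in every peak and gives no measured summit, so peak centres were taken as midpoints. The longer list of each sample held peaks whose lowest deposited false discovery rate (a q-value of the local cut rate) was at most 0.05, and the shorter list at most 0.001, as tested on the files. The longer list was used, with 144270 and 124426 peaks, and the shorter one (87039 and 74088) as an alternative. The false discovery rate file lists only intervals at 0.05 or less. The footprint files hold the constant 0.01 in every row, which the authors deposited with no name (read as a p-value or q-value threshold), so footprints could not be ranked.

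Gene models were GENCODE M21 (basic set) and sequence was GRCm38, whose chromosomes match mm10. Promoters were windows of 1000 bp to each side of every start site of a protein-coding transcript. A start site outside that set, or a peak just beyond the window, leaves a gene without a promoter peak. All 379 list entries (370 distinct symbols) were matched, 2 through synonyms. Overlaps of 1 bp or more counted as shared (bedtools 2.31.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with sequence indexed by samtools 1.23.1). Peaks were paired for height where each was the other's best overlap. Counting error was described with an exact two-sided binomial test of the whole steps of each pair, given the totals of all pairs, which treats 1 step as 1 cut. Cuts that come from the same fragment or amplification are not independent, so it covers counting error only.

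The following choices were made before the data were examined: 28 gene lists (12 of cell types of the hippocampus and choroid plexus, the rest of pathways, complexes, other organs and regions and developmental regulators), 20 motifs as exact consensus strings, the tests, and the genes to name. The text names up to 4 members of each list with the strongest promoter peak and up to 2 with none, the 10 genes with the strongest promoter peaks, the 10 with the most shared distal peaks, the 5 strongest promoters called in each replicate alone and the 5 strongest intergenic peaks. Some genes that this rule takes are not reported here. Promoter lists were compared with 10000 random lists matched on decile of the CpG observed/expected ratio (500 bp to each side of a start site, the highest of a gene), distal lists with lists matched on decile of gene length, and replicate differences with lists matched on decile of mean height, for lists with at least 3 members measured in both replicates. With 2 samples of 1 group no test between conditions was possible and no p-value is given.

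Motif matches on either strand were counted in 200 bp windows at peak centres and in windows 1000 bp to each side that touched no peak of either replicate. The odds ratios add 0.5 to each cell. A motif was called higher or lower when both replicates and at least 15 of 20 chromosomes (all but Y) had the same side of 1. Footprints inside peaks were compared with a random window of the same length in the same peak outside every footprint. Very low counts limit NFI, REST and HNF1, whose long consensus strings match few sites. Shuffled motifs, 10 per motif and 7 for SP/KLF, kept the letters and the number of CG.

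The functions were tested on simulated data. For the overlap of peaks, a planted share of 69.7% of 47460 peaks was recovered as 69.7%. For the gene lists, on 21803 genes, 5.25% of random lists of 15 genes fell outside the range and 93.0% of lists with 6 opened promoters were called. For replicate differences a planted log2 change of 0.50 in 200 of 21803 genes was recovered as 0.50, and for motifs a planted odds ratio of 11.7 over 20000 windows as 11.9. Further copies of tall peaks were searched with blastn 2.17.0 at 90% identity over 80% of the length. Figures were drawn with matplotlib 3.10.9.

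Alternatives covered the overlap, the peak list, the stronger part of the peaks, window and flank sizes, matching, scaling, motif windows and backgrounds, and leaving out each replicate.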

Results

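Chromatin accessibility was mapped by DNase-seq in the adult mouse hippocampus (tissue label: layer of hippocampus, with no layer named). DNase I cuts DNA where it is not protected by nucleosomes or bound proteins, so clusters of cuts (peaks) mark accessible promoters and distal elements, and short protected stretches inside them (footprints) mark candidate protein binding sites. The series held 1 group of 2 biological replicates, each a pool of 2 biosamples from male mice aged 8 to 10 months of the strain B6CASTF1/J, a cross of C57BL/6J with CAST/EiJ. There was no second condition, so the comparisons were between the replicates, between gene lists and between sequence motifs. Replicate 1 had 144270 peaks and replicate 2 had 124426, with a median length of 200 bp in each. The median peak height was 0.643 in replicate 1 and 0.639 in replicate 2, in the authors' units, which equalled 98 and 99 of the smallest steps between heights (the value of 1 cut if heights are scaled cut counts). Footprints numbered 348892 and 327771. The total number of cuts per sample was not analysed here, but the steps were nearly equal (152 and 155 steps per unit of height), which put the replicates at similar depth if both were scaled the same way. Values below are given as mean ± SD with n = 2 replicates unless each replicate is named, and positions are in the mm10 build.

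The first comparison was whether the replicates gave the same map. The 10 promoters with the highest mean height had a peak in both replicates. They included those of Hjurp (a chaperone of centromeric histones; height 25.6 ± 5.13), Acin1 (18.6 ± 5.30), Rab11b (17.8 ± 2.96), Ankhd1 (17.4 ± 2.55), Bahcc1 (17.1 ± 3.71), Hnrnpc (17.0 ± 2.01) and Dnpep (16.7 ± 4.93), and all 10 were higher in replicate 1. Also among them were Gm21887 on chromosome X (21.1 ± 0.689) and 1700123O20Rik, which shares its promoter peak with Acin1. Of the peaks of replicate 1, 72.3% were overlapped by 1 bp or more by a peak of replicate 2, and of the peaks of replicate 2, 84.1% were overlapped by a peak of replicate 1 (mean 78.2% ± 8.30). After 100 random shifts of the peaks along their chromosomes the share was 1.95% on average (1.83 to 2.04). The base Jaccard index was 0.549. The 72.3% and 84.1% count 1 overlap from each side, so their SD reflects unequal peak numbers and not spread between replicates. With equal numbers of peaks the mean share was 79.1% ± 0.224.

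Sharing followed peak height. In the lowest decile of replicate 1 peaks by height 27.5% were found in replicate 2, and in the highest decile 99.5%. The same shares for replicate 2 peaks were 47.6% and 99.6%. Only 14.4% of the 39904 unshared peaks of replicate 1 held any base that the other replicate's false discovery rate file listed at 0.05 or less, against 25.1% of the 19816 unshared peaks of replicate 2. Across 101938 pairs of peaks matched between replicates, Spearman's rho of height was 0.947 and Pearson's r of log2 height was 0.959 (across peaks, which are not independent replicates). Heights were lower in replicate 2 (median log2 ratio −0.19). After scaling to that median 99.4% of pairs lay within 2-fold. Given the total of all pairs in each replicate, 30.2% of pairs differed beyond the range that counting error alone leaves in 5% of pairs, if 1 step is 1 cut.

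**Figure D1:**
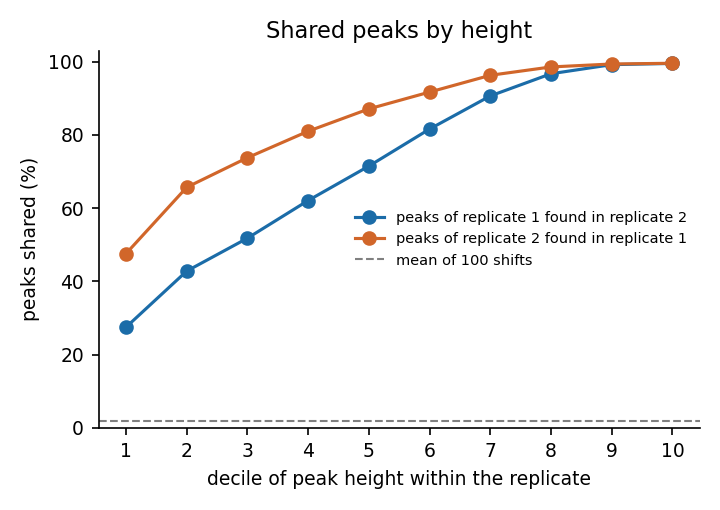
Share of the peaks of each replicate found in the other (vertical axis, %) by decile of peak height within the replicate (horizontal axis, lowest to highest). The share rose from 27.5% to 99.5% for replicate 1 and from 47.6% to 99.6% for replicate 2, and the dashed line marks the 1.95% found after random shifts.

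A few regions were unequal, and those named were chosen after their values were seen. In 100 kb of Shisa6 on chromosome 11 replicate 1 had 45 peaks and replicate 2 had 3, whereas in 100 kb of the NMDA receptor gene Grin2a on chromosome 16 the numbers were 18 and 67. Over 3818 regions of 100 kb with at least 20 peaks, replicate 2 gave a median of 47.6% of the peaks.

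**Figure D2:**
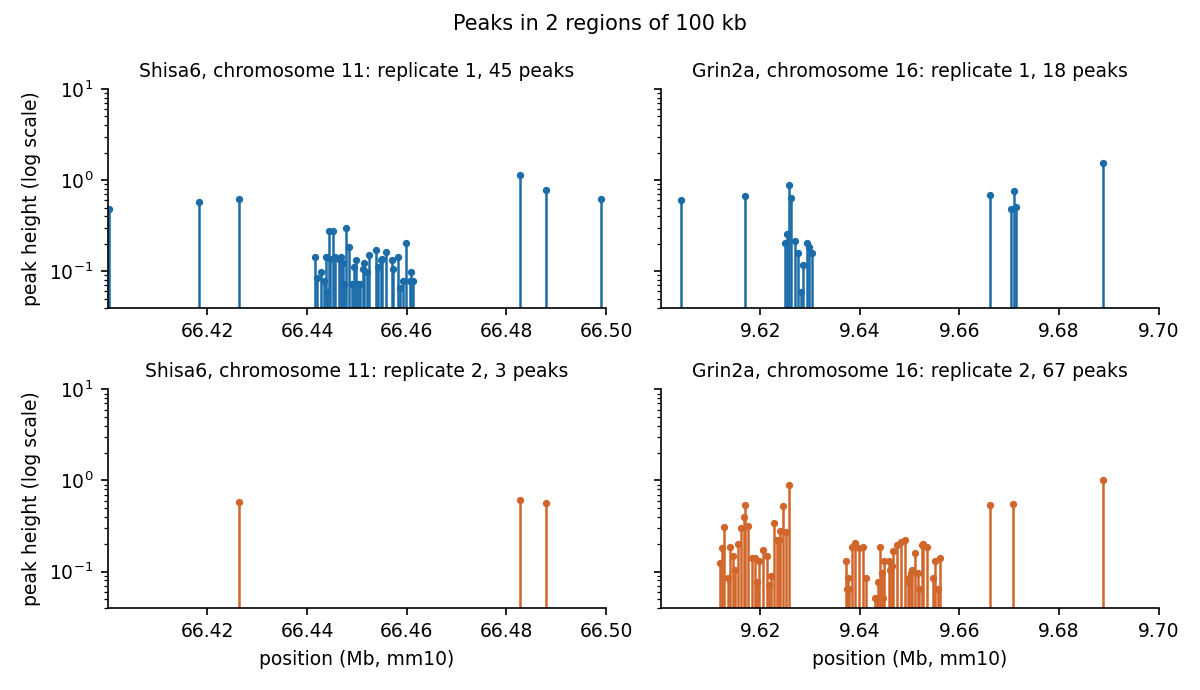
Height (vertical axis, log scale) and position (horizontal axis, Mb) of the peaks of replicate 1 (upper panels) and replicate 2 (lower panels) in 100 kb of Shisa6 (left) and Grin2a (right). The richer replicate had runs of closely spaced low peaks, with a median height of 0.131 in replicate 1 at Shisa6 and 0.149 in replicate 2 at Grin2a.

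Few promoters were called in 1 replicate alone. Of 21803 protein-coding genes, 13650 (62.6%) had a promoter peak in both replicates, 497 in replicate 1 alone, 240 in replicate 2 alone and 7416 in neither, with a promoter taken as 1000 bp to each side of any annotated protein-coding start site. The strongest promoter peaks of replicate 1 with no counterpart included those at March9 (height 1.86), Agap2 (1.60), Dtx3 (1.52) and Hr (1.42). March9, Agap2 and Dtx3 lie close together on chromosome 10, where replicate 2 also had fewer peaks within 50000 bp (8 against 23 around March9). Those of replicate 2 were at Gm11168 (1.59), Amigo1 (0.994), Oscar (0.994), Cpne7 (0.872) and Tmem88 (0.859). The peak of Oscar had its 180 bp listed in the false discovery rate file of replicate 1, so there the difference lay in the peak call.

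The second comparison was where in the genome the accessible sites lay. Promoters held 19.6% ± 1.49 of peaks, against 2.30% after random shifts, and exons outside promoters 5.86% on average against 3.55%. Introns held 40.5% against 41.8% after shifts, and intergenic sequence 34.0% against 52.4%. Promoter peaks were taller than other peaks, with a median height of 1.24 against 0.584 in replicate 1 and 1.11 against 0.581 in replicate 2. The promoter share rose to 28.4% among the stronger part of the peaks (those at or above the median height). Open promoters followed CpG content: 6.38% of genes in the lowest decile of CpG observed/expected ratio had a promoter peak in replicate 1, and 97.6% in the highest. Chromosome X was sparse, with 22.1 peaks per Mb against 57.0 on the autosomes in replicate 1 and 19.8 against 49.1 in replicate 2, and its median height was 0.566 and 0.570 of the autosomal median. The mice were male, with 1 copy of X per cell, and no correction for copy number was made here. These values therefore do not show that X was less accessible per copy. The lowest autosome, chromosome 3, had 47.1 and 40.2 peaks per Mb and the highest, chromosome 11, had 76.9 and 66.4.

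Some of the tallest peaks outside promoters lay on sequence that occurs more than once in the genome. The tallest was on chromosome 17 at 39846781 to 39846920 (height 54.1 ± 4.22), in the ribosomal RNA gene CT010467.1. This peak was singled out after its values were seen. The strongest intergenic peak was on chromosome 3 at 5860361 to 5860530 (33.5 ± 2.23), 109065 bp from the nearest coding gene, Gm8797, and had 15 further copies in the reference. The others among the 5 strongest were on chromosome 6 at 49236421 to 49236620 (24.1 ± 4.63, nearest gene Tra2a), on chromosome 8 at 20122141 to 20122320 (19.7 ± 0.312) and at 20424721 to 20424940 (18.2 ± 1.39, in the pseudogene 2610005L07Rik), and on chromosome 16 at 4541861 to 4542120 (15.5 ± 2.80, 44 bp from Srl). The last had no further copy and the others had 2, 5 and 6. The 10 genes with the most distal peaks present in both replicates, a count that grows with the annotated length of a gene, included Gm20388, Fgfr2, Asic2, Dlg2, Rbfox1, Lsamp, Auts2, Camta1 and Csmd1. The gene model of Fgfr2 ran from 130162451 to 133123350 on chromosome 7, and its 232 and 194 distal peaks came to 0.715 per 10 kb.

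The third comparison was which genes were accessible, by lists fixed before the data were examined. Each list was set against 10000 random lists of protein-coding genes with promoters of like CpG content, and its share of open promoters was taken as high or low when it fell in the top or bottom 2.5% of those lists. This describes these libraries and carries no p-value, and 1.4 of 28 lists would fall outside by chance. Promoters of excitatory neuron genes were open throughout: 12 of 12 in both replicates (percentile 99.8), with the calcium/calmodulin-dependent kinase gene Camk2a at 3.94 ± 0.699, Neurod2 at 3.31 ± 0.521 and Nrgn at 3.16 ± 0.621. The synaptic vesicle list had 16 of 16 open (98.4), led by Rab3a (7.28 ± 2.10), Syt1 (4.42 ± 0.769), Syn2 (4.41 ± 0.764) and Vamp2 (4.21 ± 0.628). The postsynaptic density list had 16 of 16 (99.9), led by Nlgn2 (7.77 ± 2.30) and Homer1 (7.45 ± 1.54). GABA-A receptor genes had 12 of 13 open in both (99.0), with Gabra2 at 2.53 ± 0.0199 and no promoter peak at Gabra6, the cerebellar subunit. Forebrain transcription factor genes had 19 of 20 (99.4), with Pou3f3 at 8.06 ± 1.83 and Id2 at 7.67 ± 1.97. The forebrain call was lost when only gene 5′ ends were taken as start sites.

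Oligodendrocyte and astrocyte genes were also open. The oligodendrocyte list had 12 of 14 promoters open in both replicates (percentile 99.98), with the myelin gene Mbp at 2.53 ± 0.305, Cnp at 1.93 ± 0.708, Olig1 at 1.93 ± 0.243 and Myrf at 1.77 ± 0.416. The astrocyte list had 10 of 12 (99.8), with Sox9 at 2.99 ± 0.591, Aldoc at 2.46 ± 0.0329 and the glutamate transporter genes Slc1a2 at 1.84 ± 0.178 and Slc1a3 at 1.09 ± 0.0356. Gfap had no peak inside the window, but its nearest peak lay 1221 bp from a start site in both replicates. The astrocyte result rested on low peaks: among peaks at or above the median height its percentile was 43.4, and by median promoter height it was 38.7. By median promoter height the GABA-A receptor list stood at 37.2 and the forebrain list at 22.8, so these lists had more open promoters than random lists without a higher median height.

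Markers of the hippocampal fields were mostly open without standing apart from random lists. The CA2 and CA3 pyramidal cell list had 9 of 12 open in both replicates (88.6), with Elavl2 at 7.36 ± 0.840, Pcp4 at 4.50 ± 0.0587, Nectin3 at 3.74 ± 0.453 and the kainate receptor gene Grik4 at 3.17 ± 0.0188, and no peak at Iyd. The CA1 list had 6 of 8 (83.7), led by Wfs1 (6.04 ± 1.64) and Pou3f1 (3.20 ± 0.667), and the dentate granule cell list 7 of 10 (78.5), led by C1ql3 (3.51 ± 0.183) and C1ql2 (1.98 ± 0.515). Neither Lefty1 nor Lct had a promoter peak. Ionotropic glutamate receptor genes had 16 of 17 (91.6), with Gria2 at 3.85 ± 0.675 and Grin1 at 3.37 ± 0.531 and no peak at Grin2c. Immediate early genes, which neuronal activity induces, had 17 of 17 (91.3), led by Jun (13.4 ± 2.23), Jund (9.14 in replicate 1 and 7.45 in replicate 2), Egr1 (7.58 ± 0.768) and Homer1 (7.45 ± 1.54). Housekeeping genes had 15 of 15 (87.5), led by Rplp0 (14.9 ± 0.830) and Rpl13a (11.7 ± 2.55).

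Inhibitory neuron genes had fewer open promoters than random lists. They had 8 of 16 open in both replicates (percentile 0.425), with Gad1, which makes GABA, at 1.38 ± 0.0665 and no peak inside the window at Dlx1 and Dlx2. The nearest peak in replicates 1 and 2 lay 1497 and 1527 bp from a start site of Dlx1, and 16935 and 1248 bp from Dlx2. Within the range of random lists were oligodendrocyte precursor (6 of 9 open in both, percentile 38.6; Pdgfra 2.07 ± 0.239), microglia (4 of 14, percentile 95.4; Csf1r 0.527 ± 0.00314), endothelial cell (2 of 12, percentile 10.1; Kdr 0.547 ± 0.0339), mural cell and fibroblast (5 of 12, percentile 62.2; Col1a1 2.83 ± 0.119) and choroid plexus and ependyma (4 of 12, percentile 49.0; Foxj1 6.25 ± 0.182, Ttr 0.772 ± 0.0963). Replicate 1 alone had promoter peaks at 5 microglial and 4 endothelial genes, and replicate 2 alone at 1 of each.

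Hox, pluripotency and germ cell genes and those of 2 other sets of brain regions had fewer open promoters than random lists. Hox genes had 1 of 23 open in both replicates (percentile 0.0), Hoxa10 at 0.563 ± 0.00734. The pluripotency and germ cell list had 2 of 12 (0.005; Pou5f1 and Nanog closed), cerebellum and hindbrain 3 of 12 (0.0; Cbln1 2.17 ± 0.619, Pcp2 closed) and thalamus and hypothalamus 6 of 12 (0.525; Pmch closed), all below random lists. Striatum and midbrain dopamine genes had 7 of 12 (15.1), with Rgs9 at 3.70 ± 0.0978 and Th, the rate-limiting enzyme of dopamine synthesis, closed. Liver had 2 of 15 (8.45; Alb closed), skeletal muscle 4 of 13 (26.5; Myod1 closed), lymphocyte 2 of 12 (49.8; Cd3e closed) and erythroid 2 of 11 (57.8; Hbb-bs closed). Without the match on CpG content, liver, skeletal muscle, lymphocyte and erythroid also stood below random lists (percentiles 0.0, 0.770, 0.105 and 0.0700), as immediate early, ionotropic glutamate receptor and housekeeping genes stood above (99.98, 99.8 and 99.96). Thalamus and hypothalamus, inhibitory neuron and astrocyte genes then lay within the range (15.2, 42.8 and 96.005).

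**Figure D3:**
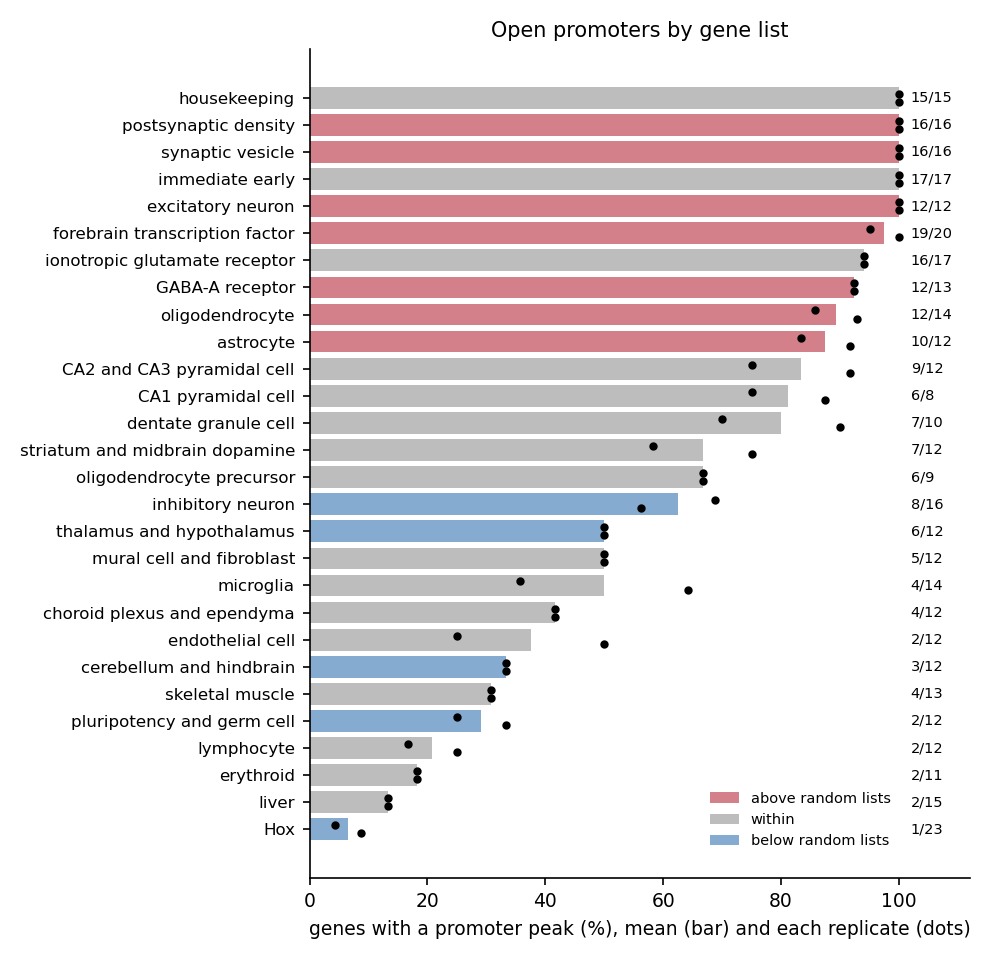
Share of the genes of each list with a promoter peak (horizontal axis, %; bars are the mean of the replicates, dots each replicate), with the number open in both over the number of genes at the right. Excitatory neuron genes stood at 12 of 12 and Hox genes at 1 of 23, and colours mark lists in the top or bottom 2.5% of random lists matched on CpG content.

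Distal peaks were then counted in and within 10000 bp of each gene, per 10000 bp. Forebrain transcription factor genes had the highest list median, 2.16 ± 0.282, followed by immediate early genes (1.59 ± 0.0642), oligodendrocyte (1.11 ± 0.0105), excitatory neuron (1.02 ± 0.240), astrocyte (0.917 ± 0.139), postsynaptic density (0.911 ± 0.296), synaptic vesicle (0.802 ± 0.118) and CA2 and CA3 pyramidal cell genes (0.781 ± 0.0452). These 8 lists were above random lists matched on gene length, and none of the other 20 lists was above or below. Microglia genes (0.698 ± 0.0695) stood at percentile 95.98 and endothelial cell genes (0.350 ± 0.0877) at 18.4. Grik4 had 48 distal peaks in replicate 1 and 51 in replicate 2, and the retinoid-related receptor gene Rora had 60 and 54.

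The fourth comparison was whether gene lists differed between the replicates at the strongest promoter peak, after scaling to the median of shared peaks. With the match on mean height none of the 22 lists with at least 3 promoters open in both replicates lay outside the range of random lists. Forebrain transcription factor genes were lower in replicate 2 at 15 of 19 members (median log2 −0.21, percentile 7.78), CA1 genes at 6 of 6 (−0.29, percentile 4.51) and microglia genes higher at 3 of 4 (0.17, percentile 93.5). The heights of the shared distal peaks in and within 10000 bp of a gene and of its strongest promoter peak were then added. This sum is called all peaks of a gene here, although distal peaks called in 1 replicate alone and further promoter peaks were left out. Over all peaks of a gene in this sense 3 lists lay outside the range. Hox (median log2 0.38, percentile 99.99) and striatum and midbrain dopamine genes (0.25, percentile 99.1) lay above and dentate granule cell genes below (−0.22, percentile 0.82). Neighbouring Hox genes count the same distal peaks, so their values are not independent, whereas random lists draw genes from the whole genome. The percentile of the Hox list may therefore overstate how far it stood apart. The promoter value of Dlg2 (1.33 in replicate 1 and 7.56 in replicate 2) came from the edge of its window, since the matching peak of replicate 1 ended just outside it.

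The fifth comparison was which transcription factor motifs the accessible sites carried. The CTCF motif, the site of the insulator protein, was the most enriched at peak centres, in 3.98% and 4.54% of them, with an odds ratio of 64.9 ± 5.89 against flanking sequence outside peaks. NRF1 (15.2 ± 1.69), EGR (13.1 ± 0.867), RFX (9.49 ± 1.27), NFI (8.92 ± 3.07), CRE (5.61 ± 0.357), ETS (5.18 ± 0.376), SP/KLF (5.07 ± 0.00158) and REST (5.06 ± 0.0304) followed. The proneural bHLH motif of the Neurod family had a smaller odds ratio (3.54 ± 0.135) and was the most common, in 13.9% and 13.4% of peaks. MYOD (2.20 ± 0.104), AP-1 (1.98 ± 0.0698), GRHL (1.74 ± 0.0576) and MEF2 (1.30 ± 0.0529) were also above 1 in both replicates and on at least 15 of 20 chromosomes, which made 14 of 20 motifs. GATA (0.486 ± 0.00633) and HNF4 (0.655 ± 0.0643) were depleted. Their shuffled motifs stood at 0.594 and 0.903, so part of the GATA value belonged to composition, and both were still called lower than these. PU.1 (1.27 ± 0.107), OCT/POU (1.05 ± 0.000681) and SOX (0.963 ± 0.0398) met neither rule, and HNF1 had no match in any peak window.

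Promoter and distal peaks carried different motifs. ETS (odds ratio 13.4 ± 0.111), SP/KLF (12.6 ± 0.198) and NRF1 (11.4 ± 0.177) were more frequent at promoters than in distal peaks, and CTCF (0.203 ± 0.0160), proneural bHLH (0.211 ± 0.0120), AP-1 (0.309 ± 0.00526) and MEF2 (0.351 ± 0.0384) less. In distal peaks alone proneural bHLH matches reached 16.2% and 15.9%. Part of the enrichment of CG-containing motifs belonged to their composition: shuffled versions with the same letters and number of CG had odds ratios of 7.92 for EGR and 6.33 for NRF1, and against shuffled versions EGR and GRHL were no longer above on enough chromosomes in both replicates, whereas OCT/POU and PU.1 were.

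The last comparison was at footprints, which covered 13.2% and 14.8% of peak bases. CTCF (39.8 ± 0.0579), NRF1 (39.2 ± 3.62), NFI (16.5 ± 7.36), EGR (13.8 ± 0.981), CRE (10.9 ± 0.622), RFX (7.09 ± 1.24), SP/KLF (6.74 ± 1.17), proneural bHLH (4.32 ± 0.837), MYOD (1.82 ± 0.150) and ETS (1.26 ± 0.0802) matches overlapped footprints more often than windows of the same length in the same peaks, 10 motifs in all. GATA (0.423 ± 0.0579) and OCT/POU (0.651 ± 0.0473) did so less often, but neither was called lower against its shuffled motifs (0.562 and 0.635). For ETS and SP/KLF the shuffled motifs reached similar odds ratios (1.34 and 5.62), whereas for NRF1 and CRE they stayed at 2.49 and 1.22. AP-1 (1.28 ± 0.207), MEF2 (0.968 ± 0.152), REST (2.73 ± 0.308), SOX, HNF4, PU.1 and GRHL met neither rule, although AP-1, MEF2 and SOX were higher than their shuffled motifs (ratios 1.82, 1.57 and 1.53), and HNF1 had no match. Within peaks shared by the replicates 59.5% of replicate 1 footprints and 58.3% of replicate 2 footprints overlapped a footprint of the other (mean 58.9% ± 0.859, 1 overlap counted from each side). After moving the replicate 1 footprints at random within their peaks the share for replicate 1 was 35.9% (35.7 to 36.1), and those of replicate 2 were not moved. The share was 80.8% and 79.3% among the footprints in the tallest of 5 classes of peak height and 38.0% and 36.8% in the lowest class. No class was set against its own moved footprints, so how much of this rise was random overlap was not tested.

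**Figure D4:**
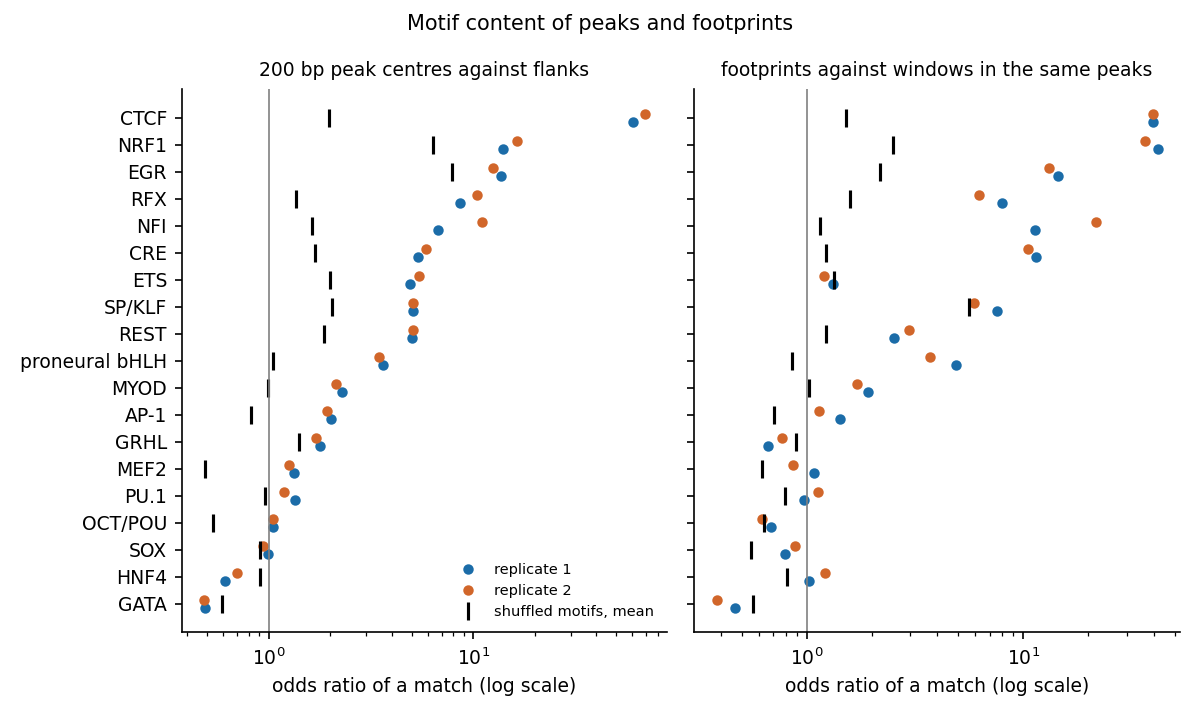
Odds ratio of a motif match (horizontal axes, log scale) at peak centres against flanks (left) and in footprints against other windows of the same peaks (right), for each replicate (dots) and for shuffled motifs (black marks, mean of the replicates). CTCF lies near 64.9 in peaks and 39.8 in footprints, and at footprints the marks of ETS and SP/KLF lie beside the dots. With control windows mirrored at the peak centre, which only part of the footprints allowed, the mean in footprints was 12.1 for CTCF and 22.4 for NRF1.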

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

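In this part, the tests of housekeeping promoters and of neuronal against other genes over all peaks, with the spread among their lists, were chosen only after the result was seen, as were the regions. So was the comparison of peaks with a CTCF match. The design gives 1 group, so no biological explanation was tested beyond the cell makeup of the pools.

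The false discovery rate files, used above to check the peak lists and peaks called in 1 replicate alone, held signal outside the peaks. Of the bases listed at 0.05 or less, 38.0% in replicate 1 (17991007 bp) and 36.7% in replicate 2 (14560443 bp) lay outside every peak of the same replicate. Over all listed bases, inside and outside peaks, the Jaccard index between the replicates was 0.662, above the 0.549 of the peaks. The bases outside peaks were not compared alone, so whether they recur between the replicates was not tested.

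A few regions held many peaks in 1 replicate and few in the other; they were picked for this after the values were seen. In 100 kb of Shisa6 (chromosome 11, from 66400001) replicate 1 had 45 peaks and replicate 2 had 3, in Zmat4 (chromosome 8, from 23800001) the numbers were 34 and 1, and in the NMDA receptor gene Grin2a (chromosome 16, from 9600001) they were 18 and 67. In the 10 most unequal regions each way, the 168 peaks called in both replicates, which by definition exclude losses, kept their height (median scaled log2 of the poorer over the richer replicate 0.081, SD 0.33), which is consistent with a local threshold of the peak calling that differed between samples but does not show one. The median height of the peaks called only in the richer replicate ran from 0.131 in Shisa6 and Zmat4 to 0.466 in another of these regions, against 0.643 for all peaks of replicate 1. A real difference in weak cutting stays open.

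Peak heights were lower in replicate 2, and among tall peaks more at promoters (median unscaled log2 ratio −0.37 in the top decile of height) than at distal peaks (−0.10), whereas in the 5 lowest deciles promoters fell no more than distal peaks. Relative to the median of all shared peaks (−0.19), excitatory neuron genes together were lower than genes of 6 other cell types together, but not list by list, since CA2 and CA3 genes (−0.036) were level with oligodendrocyte (−0.031) and endothelial cell genes (−0.030). An equal loss of enrichment in all peaks is argued against, since distal peaks with a proneural bHLH match lay lower than others of the same height (−0.071, lower on 20 of 20 chromosomes) and those with a CTCF match higher (0.27, on 20 of 20). The pooled gap was 0.18 over all peaks, 3.12 times the SD of random splits of the genes. It did not come from promoters, since it was 0.20 over distal peaks alone. The 6 lists of other cell types lay no further apart than random regroupings of their genes (SD of medians 0.075, percentile 44.6). A lower share of neurons in the pool of replicate 2 was the explanation weighed, but its test value is this gap itself. The random splits vary genes and not pools, so the gap cannot decide on the makeup of the pools. Inhibitory neuron genes, left out of this comparison, were not lower (0.13), so the lower heights did not extend to all neuronal lists. As for the lower heights as a whole, housekeeping promoters fell as well (median log2 −0.35 unscaled, lower at 14 of 15, and −0.16 scaled). This argues against a lower share of neurons, if these promoters are equally open in all cell types and both replicates were scaled alike. Their fall was close to that of all promoter peaks in the top decile of height (−0.37). The rise at CTCF sites and the fall at tall promoter peaks stay without a tested cause.

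Footprints fell on matches of several CG-containing motifs, and a possible explanation is the CG content of the sequence and not the bound factor. The odds ratio exceeded that of shuffled motifs with the same letters and number of CG by 15.8 times for NRF1, 8.98 times for CRE and 6.36 times for EGR, which argues against composition alone for these. For SP/KLF the ratio was 1.19 and for ETS 0.941, so footprints at these matches were no more, or little more, frequent than at shuffled strings. Other sequence preferences of DNase I stay open for all of them.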

How the results depend on the processing

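The tests with shuffled motifs, gene 5′ ends, median promoter heights, footprints of 10 bp or longer, mirrored control windows and reversed motifs in footprints were chosen after seeing the data, and the cause was not tested where a value moved unless a construction is named. The mean share of shared peaks was 65.2% with 50% reciprocal overlap and 86.7% among the stronger peaks. Pearson's r was 0.968 on linear heights and 0.948 among the stronger peaks, where the range of heights is narrower. The promoter share was 15.6% with 500 bp, 24.3% with 2500 bp, 28.4% among the stronger peaks and 25.6% in the shorter list, and 18.6% to 20.7% without either replicate. By median height 6 lists stood apart instead of 12 (astrocyte 38.7, GABA-A receptor 37.2 and forebrain 22.8), the forebrain list had percentile 34.3 at gene 5′ ends and the astrocyte list 43.4 among the stronger peaks. With no match on mean height 3 lists differed between the replicates instead of 0, and over all peaks of a gene also 3, of which Hox was not among the 22 lists of the main test. Against reversed motifs ETS (log2 0.30) and CRE (−0.059) were no longer called higher in peaks, GRHL (−2.43) was called lower and HNF4 (0.83) higher. OCT/POU (4.20) and PU.1 (1.30) were called higher and SOX (−0.22) lower, and OCT/POU was called higher in footprints (4.85). SP/KLF reads the same reversed, so that background is void for it. For the other motifs it compares 2 different strings in the same windows, so it cannot tell enrichment from rarity of the reversed string. In replicate 1 OCT/POU matched 1.30% of peaks and its reversed string 0.0714%, but flanking windows held 1.24%. Against shuffled motifs ETS (−0.089) and OCT/POU (0.032) changed side at footprints, as did MEF2 (0.64) and SOX (0.61), which with AP-1 (0.85) were then called higher, and GATA was no longer called lower (−0.42), nor with mirrored windows (−0.90) or reversed motifs (−0.42). With mirrored windows ETS (log2 0.35) and OCT/POU (−0.38) also lost their call and AP-1 (0.31) gained one. CTCF moved from log2 5.31 to 3.60 with these windows, below NRF1 (from 5.29 to 4.45). Mirroring also left out footprints whose mirrored window touched a footprint, so 188146 instead of 298050 were compared in replicate 1. Of these 0.730% overlapped a CTCF match, against 1.73% before, and of the control windows 0.0648% against 0.0440%. The move therefore reflects other footprints as well as another control. Footprint sharing was 43.0% with 50% reciprocal overlap and 63.2% for footprints of 10 bp or longer. Numbers of lists with high or low distal density and of enriched motifs stayed within 1.5 times under every alternative run for them, and without either replicate they ranged from 11 to 12 lists at promoters, 7 to 10 distal lists, 14 to 15 motifs in peaks and 10 to 11 in footprints. Values of single lists or motifs kept their call, or stayed without one whatever their side, 159 times and gained or lost a call 4 and 5 times for distal density, against 192, 13 and 14 times at promoters, 142, 8 and 7 for motifs in peaks and 97, 13 and 7 in footprints, and in these last 3 sets values called in the main result changed direction 5, 3 and 3 times. The stronger part of the footprints could not be taken, since the deposited footprints carry no score. No paired analysis was possible because the series holds 1 group. In the lowest height decile of each replicate 27.5% and 47.6% of peaks were shared, and whether depth set this was not tested.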

Other observations

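In this part the motif tests between the replicates, other than that of the proneural bHLH motif in shared peaks, were chosen only after the result was seen.

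Distal peaks called in 1 replicate alone differed in motifs. Proneural bHLH matches were in 14.2% of the 35495 distal windows of replicate 1 alone and in 10.8% of the 16544 of replicate 2 alone (odds ratio 0.730, below 1 on 20 of 20 chromosomes), AP-1 matches in 7.51% and 6.06% (0.795) and SP/KLF matches, a motif of many promoters, in 0.842% and 0.568% (0.675, below 1 on 16 chromosomes). CTCF matches went the other way, 0.952% and 1.55% (1.64, above 1 on 18 chromosomes), as did REST, the repressor of neuronal genes in other cells (0.0282% and 0.127%, few sites). In shared distal peaks the SP/KLF (−0.14), RFX (−0.10), MEF2 (−0.10) and AP-1 (−0.08) matches also went with lower heights in replicate 2 than other peaks of the same height, on at least 19 of 20 chromosomes each.

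Very tall peaks outside promoters are a candidate for reads gathered from several copies of a sequence. Of the 20 tallest, 9 (45.0%) aligned to another place of the reference, against 2 of 200 random shared peaks outside promoters and 2 of the 20 tallest promoter peaks. The share was under the 50% set beforehand for that explanation and above the 20% that would argue against it, so the test leaves it open, and copies missing from the reference could not be seen. Of these 9 peaks, 8 were higher in replicate 2, as were 3 of the 11 with no further copy.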
